A study of Mus musculus with 2 samples.

How the data were processed

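Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in mouse liver at embryonic day 15.5. There was 1 group with 2 biological replicates, per the labels: a pool of livers from 78 embryos (replicate 1) and a pool from 62 embryos (replicate 2), both of strain B6NCrl and of mixed sex. Replicate 2 had 2 technical replicates and replicate 1 had 1, per the labels, which name the pools as separate biological replicates. There was no second group, so no comparison of conditions was possible and no pairing applied.

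The authors deposited 4 peak lists, all on the mm10 assembly per the descriptions deposited with them: a list called on each replicate alone, a list called on the alignments of both replicates pooled, and a list named replicated peaks that was derived from the pooled list and both replicate lists. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries the authors' own value of fold enrichment, a linear ratio read here as enrichment over the control library. That reading comes from the narrowPeak column order and from the values, since the lists have no header and no description defines the column. Each peak also carries the −log10 of a p-value and of a q-value, as deposited by the authors. The lowest −log10 p-value was 2.01 in both replicate lists, so these lists hold peaks with p below about 0.01 and were not filtered on q. The fold enrichment was used only to describe, rank or filter peaks within a list, and fold values of different lists were not compared. The files give no read counts, so the depth of each library is unknown and no interval that needs it is given.

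Peaks on the 19 autosomes and the X and Y chromosomes were analysed, and all lay within the chromosome lengths of the GRCm38.p6 sequence, the same assembly as mm10. Genes and transcription start sites (TSSs) were taken from GENCODE release M21: 21853 protein-coding genes with 54361 TSSs of protein-coding transcripts. Coordinates are 1-based. Overlap meant at least 1 bp unless another limit is given. Overlap of the replicates and the location of peaks were compared with 1000 circular shifts of the peaks along each chromosome, by a one-sided permutation test whose smallest possible p is 0.000999. The shifts also place peaks in assembly gaps and unmappable sequence, which lowers the overlap they give. A promoter was marked where a replicated peak overlapped the window of 1 kb either side of any TSS of the gene. Its fold enrichment was the highest of any such peak, and a peak in the windows of neighbouring genes counted for each. Each gene list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 31 lists at 0.05. Domains were made from replicated peaks not wholly within 2 kb of a TSS, so that wide promoter peaks stayed in them, joined across gaps of at most 12.5 kb and ranked by the sum of fold enrichment times width. The highest 500 were assigned to the protein-coding gene with the TSS nearest to their midpoint, which is a neighbour and not a shown target. Motifs were counted in windows of 500 bp at the midpoints of distal replicated peaks, those that overlapped no promoter window, against 1 window per peak of the same chromosome and the same 2.5-point bin of GC percentage, outside all pooled peaks. Of 37125 distal peaks, 37123 had such a window, with mean GC contents of 47.8% and 47.7%. Motif ratios carry 95% intervals and Fisher's exact tests, with Benjamini-Hochberg adjustment over 23 consensus sequences, and 20 shuffled versions of each sequence were counted the same way, or as many as could be counted. Intervals on shares of peaks are Wilson intervals and those on shares of genes are exact Clopper-Pearson intervals, at 95%, and all cover counting error only. Genes, peaks and windows are not replicates, so every such test describes these peak lists.

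The tests, the 31 gene lists (28 given as symbols and 3 as name patterns), the motifs, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be outside that plan or chosen later. The rule names, in each list, up to 4 marked members with the highest fold enrichment at the promoter and up to 3 unmarked members in alphabetical order, the nearest genes of the 20 highest domains, and genes whose promoters the 10 widest peaks overlap. Names outside the rule are said to have been chosen later. Older symbols were matched through the RefSeq gene table, and 1 listed symbol, Ahsp, matched no gene. Afp, Trf, Hoxa9 and Rplp0 each stand in a pair of lists. Members of the globin, Hox and ribosomal protein families have near-identical copies, and their values are uncertain where reads could be split between copies. Alternatives included other promoter windows, stricter peak thresholds, the pooled list, each replicate's list alone, random lists matched on promoter CpG content in 10000 draws with a two-sided permutation p, other joining gaps and rankings, and other motif backgrounds. Alternatives added after the data were seen were a background without olfactory receptor genes, assignment of domains by any TSS within 25 kb, a background of marked genes only, long non-coding RNA TSSs, domains without any peak that overlapped the 2 kb either side of a TSS, and a ranking of domains by highest fold.

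The replicate overlap, the gene list test, the motif counts and the joining of domains were tested on simulated data. The other procedures were not simulated. For the replicate overlap, 20000 peaks with 60% planted as shared gave an excess over shifted lists of 59.1 percentage points, and 7.5% of 40 pairs of unrelated lists of 5000 peaks gave p of 0.05 or less. For the gene lists, with 21853 genes, 90% of lists with 95% of members marked were called higher and 1.32% of unaltered lists were called. There each other gene was marked independently at a rate of 50%. The dependence of marking on promoter CpG content and peaks shared by neighbouring genes were not simulated, so the 1.32% does not cover them. For the motifs, with 6000 windows, a planted ratio of 1.38 was recovered as 1.38, which checked the counting of sites and not the GC matching or the test. For the domains, all 50 planted clusters were found in their planted order. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Peaks on the mitochondrial genome and on unplaced sequences were left out of the comparisons, and the display score of each peak was not used.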

Results

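H3K27ac peaks were mapped in livers of mouse embryos at day 15.5, in 1 group of 2 biological replicates, each a pool of embryos. The list of replicate 1 held 80253 peaks covering 47.9 Mb, and that of replicate 2 held 92212 peaks covering 48.5 Mb. The list called on pooled alignments held 100868 peaks, and the replicated list, on which the genes below are described, held 52608 peaks covering 52.9 Mb, or 1.94% of the genome. Replicated peaks had a median width of 604 bp and a median fold enrichment of 3.98, with a highest value of 69.4, where fold enrichment is the authors' own value for each peak. The depth of the libraries is unknown, since the lists give no read counts.

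The first comparison asked how far the replicates shared their peaks. Of replicate 1's peaks, 67.0% overlapped a peak of replicate 2, and of replicate 2's peaks, 61.4% overlapped a peak of replicate 1. Shifted lists overlapped by 3.52% and 3.23% (one-sided permutation p = 0.000999 in both directions, the smallest that 1000 shifts can give). With each list split into 10 equal groups by fold enrichment, sharing was 38.5% (95% Wilson interval 37.4% to 39.6%) in the weakest group of replicate 1 and 100% in the strongest, and 31.2% (30.2% to 32.1%) and 100% for replicate 2. Requiring that each peak cover at least 50% of the other reduced the shares to 41.4% and 36.0%, against 0.600% and 0.523% in shifted lists.

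**Figure D1:**
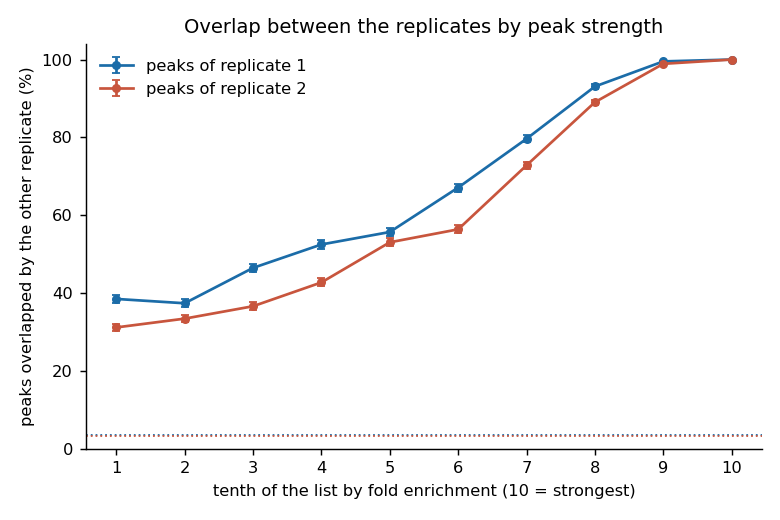
Percentage of each replicate's peaks overlapped by the other replicate (vertical axis) in 10 equal groups of its list by fold enrichment (horizontal axis, 10 strongest), with 95% Wilson intervals; dotted lines show the mean of shifted lists. The share is 38.5% and 31.2% in the weakest group and 100% in the strongest.

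Of the pooled peaks, 43866 shared at least 50% of either peak's length with a peak of both replicates, and all of them were in the replicated list. Another 8742 replicated peaks, 16.6% of that list, did not meet this measure, and 252 of them overlapped both replicates by at least 1 bp. These peaks were weaker, with a median fold enrichment of 3.08 against 4.42 for the others. How such peaks entered the replicated list is not given in the sources used here.

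Replicated peaks were concentrated at promoters. Of 52602 peaks on the main chromosomes, 29.4% lay within 1 kb of a TSS of a protein-coding transcript, 7.82 times the 3.76% of shifted peaks. Gene bodies held 46.1% of peaks against 38.4% shifted, and sequence between genes held 24.5% against 57.8% (permutation p = 0.000999 for each, the smallest possible). Promoter peaks were wider, with a median of 932 bp against 528 bp in gene bodies and 539 bp between genes, and had a median fold enrichment of 6.91 against 3.59 and 3.76. Any overlap with a promoter window placed a peak at promoters, which favours wide peaks, so part of the difference in width may come from this rule. The widest peak, of 52012 bp, covered the promoter of Zfpm1, which encodes the GATA1 cofactor FOG1, on chromosome 8 from 122280439 to 122332450. In the replicate lists that region was split into 5 and 7 peaks, the widest of 25667 bp and 17694 bp. The other 9 of the 10 widest peaks measured 18508 to 23559 bp, and 8 of them overlapped the promoters of Ank1, Rbm38, Hemgn, Foxo3, Cd82, Sema4b, Pnpo and Fam53b, while the remaining peak overlapped Nprl3 but no promoter.

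A replicated peak marked the promoters of 11070 of 21853 protein-coding genes (50.7%), and fixed gene lists were used to describe which genes these were. Erythroid genes were marked almost without exception. All 14 erythroid transcription factor and cofactor genes were marked (adjusted p = 0.000348, two-sided Fisher's exact test, written below as exact), including Klf1 with a fold enrichment of 37.0, Tal1 with 37.8, Nfe2 with 36.4 and Zbtb7a with 38.2. Klf1 lies on chromosome 8 from 84901928 to 84905291 and Hmbs on chromosome 9 from 44336339 to 44344228. Of 29 genes for globins, red cell membrane proteins and related proteins, 28 were marked (exact adjusted p = 9.56e-07), with Ank1, encoding the membrane skeleton protein ankyrin, at 44.1, Trim10 at 40.7, Rhd at 40.5 and Icam4 at 38.2, whereas Car1 was unmarked. Of 13 heme synthesis genes, 12 were marked (exact adjusted p = 0.00711), with Hmbs at 47.1, Alad at 40.9, Uros at 39.3 and Slc25a38 at 36.3. The promoter of Slc25a37, which encodes a mitochondrial iron importer, was unmarked in the replicated list and in both replicate lists. Its locus did carry the mark, in a domain of 14 replicated peaks with a mean fold enrichment of 3.53. The midpoint of that domain lay 38.7 kb from the TSS.

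Hepatocyte genes other than those of mature metabolism were widely marked. All 24 genes for plasma proteins were marked (exact adjusted p = 9.56e-07), with the highest values at Rbp4 (13.9), Apoa2 (13.4), Ahsg (10.9) and Apoe (10.8). Rbp4 lies on chromosome 19 from 38116629 to 38125281 and Cebpa on chromosome 7 from 35119293 to 35121928. Among hepatocyte transcription factor genes, 19 of 20 were marked (exact adjusted p = 0.000158), with Cebpa at 11.5 and Cebpb and Hhex both at 10.6, and Nr0b2 unmarked. In the stronger part of the peak list that call was lost (exact adjusted p = 0.0589). Complement and coagulation genes were marked in 16 of 20 cases (exact adjusted p = 0.0195), led by F11 (7.96), F10 (7.81), Masp1 (7.22) and Cfb (6.49), and C9, F9 and Kng1 were unmarked. The complement call was lost with only replicate 1's list (exact adjusted p = 0.154), with a 500 bp window, with a stricter q and in the stronger part of the list. All 15 genes of sterol and fatty acid synthesis were marked (exact adjusted p = 0.000213), with Hmgcr, which encodes the rate-limiting enzyme of cholesterol synthesis, at 21.0, Fdft1 at 17.3, and Srebf2 and Dhcr7 both at 15.3.

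The median fold enrichment of marked promoters was 29.1 for erythroid transcription factors, 28.2 for globin and red cell genes and 33.1 for heme synthesis. It was 5.45 for plasma proteins, 5.90 for hepatocyte transcription factors, 4.88 for complement and coagulation genes, 12.1 for sterol and fatty acid synthesis and 4.86 for adult liver metabolism, against 10.7 over all marked genes. Among 10000 random sets of marked genes of the same size, the erythroid transcription factor median was above 100% of sets, the plasma protein median above 0.07%, that of sterol genes above 67.1% and that of adult liver metabolism above 0.19%. This comparison was not among the tests fixed beforehand, and its sets were not matched on promoter CpG content. The median ratio of observed to expected CpG was 0.248 for plasma protein, 0.211 for adult liver metabolism and 0.258 for globin and red cell genes. Within the list of replicate 1 the erythroid transcription factor and plasma protein lists had median percentiles of 89.1 and 20.6 among marked promoters, and within that of replicate 2 they had 93.6 and 23.1.

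Metabolic genes of the mature hepatocyte were marked in 13 of 26 cases, with 50.7% in other genes (exact adjusted p = 1). Glul, which encodes glutamine synthetase, had a fold enrichment of 43.5, Asl had 16.8, Abcb11 had 6.34 and Aldob had 6.03, while Baat, Cps1 and Cyp1a2 were unmarked. Against random lists matched on promoter CpG content, of which 25.5% were marked on average, the list was higher (permutation adjusted p = 0.012). Iron handling genes were marked in 10 of 13 cases (exact adjusted p = 0.125), among them Slc11a2 (34.7), Fth1 (33.7), Ftl1 (26.7) and Tfrc (21.1), and Bmp6 and the hepcidin genes Hamp and Hamp2 were unmarked. The iron list passed against CpG-matched lists (permutation adjusted p = 0.00413). Fetal growth genes were marked in 9 of 13 cases (exact adjusted p = 0.319), with Igf2bp3 at 27.9, Igf2 at 7.07, Peg3 at 6.93 and Grb10 at 6.49, and Cdkn1c, Gpc3 and Mest unmarked. With replicate 1's list alone the fetal growth list passed (exact adjusted p = 0.0383).

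Genes used by most cells were marked. The lists were cell cycle genes, 19 of 19 (exact adjusted p = 2.01e-05, with Mcm7 at 23.7, Ccnb2 at 22.6, Ccna2 at 22.6 and Mki67 at 21.1), housekeeping genes, 14 of 14 (exact adjusted p = 0.000348, with Ywhaz at 35.7, Actb at 33.8, Ubc at 29.4 and Tubb5 at 24.9), and ribosomal protein genes, 77 of 80 (exact adjusted p = 2.91e-18). Rpl7 (37.1), Rpl27a (29.9) and Rplp1 (26.8) led the ribosomal list, and Rpl10l, Rpl39l and Rpl3l were the 3 unmarked members.

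Lists for other blood and liver cell types did not pass the test, apart from lymphoid genes, which were lower (1 of 13, Cd3d 4.22; exact adjusted p = 0.00385). The lymphoid call was lost against CpG-matched lists (permutation adjusted p = 0.0585) and with a 2 kb window (exact adjusted p = 0.0790). Marked members numbered 6 of 14 megakaryocyte genes (Gp9 22.5, Gp1ba 15.0), 8 of 14 stem and progenitor genes (Lyl1 31.2, Etv6 16.1, Runx1 15.1), 7 of 14 granulocyte genes (Cebpe 5.60, Prtn3 4.72) and 6 of 16 macrophage genes (Cd68 20.4, Id3 6.75). Endothelial genes were marked in 5 of 15 cases (Eng 6.05, Pecam1 4.17), stellate and mesenchymal genes in 4 of 16 (Reln 18.1, Vim 9.76) and bile duct genes in 2 of 9 (Jag1 7.07, Hnf1b 5.01). Replicate 1's list alone marked 8 megakaryocyte, 9 granulocyte and 8 endothelial genes and replicate 2's alone 8, 10 and 6, so these differences from other genes turned from below to above, except that of endothelial genes with replicate 2's list, and none passed. Either replicate's list alone marked 2 of the 13 lymphoid genes, with the call kept. Gata2, Flt3, C1qa, Col1a2, Acta2, Krt19 and Epcam were among the unmarked members. For the lists that did not pass, adjusted p ran from 0.0684 for stellate genes to 1 for granulocyte genes (Fisher's exact test), and stellate genes were lower against CpG-matched lists (permutation adjusted p = 0.0203).

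Genes of other organs were rarely marked. No promoter of 17 muscle genes was marked, which allows a share of up to 19.5% (exact 95% interval; exact adjusted p = 2.68e-05). Marked shares were 2 of 17 for neuronal genes (Gfap 20.1, Mbp 8.67; exact adjusted p = 0.00297), 1 of 11 for kidney (Slc12a3 10.2; 0.0111), 1 of 12 for pancreas (Cela1 6.13; 0.00676), 2 of 12 for germ cells (Gdf9 15.8, Dazl 3.98; 0.0323) and 5 of 39 for Hox genes (Hoxb4 7.22; 6.54e-06). Lung (1 of 10, Foxp2 2.96; exact adjusted p = 0.0185) and epidermal genes (1 of 10, Krt10 10.8; 0.0185) were also lower, but neither passed against lists matched on promoter CpG content. Of 1092 olfactory receptor genes, 4 were marked (0.366%, exact 95% interval 0.0999% to 0.935%), with Olfr56 at 24.5. Values of single genes here may come from promoters of neighbouring genes, since any peak in the window was counted. The value of Gfap, however, equalled the highest fold enrichment of a domain of 3 peaks that lay inside the gene. A domain of 23 peaks overlapped Mbp. Each replicate's list alone marked 2 of 10 lung genes and ended that call, and replicate 2's marked no kidney gene and 7 olfactory receptor genes. Intestinal genes, 2 of 10 (Ascl2 5.03, Lgr5 4.13), did not pass the test (exact adjusted p = 0.0875), but were lower with a 500 bp window (exact adjusted p = 0.00403), where the germ cell call was lost (exact adjusted p = 0.0597).

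**Figure D2:**
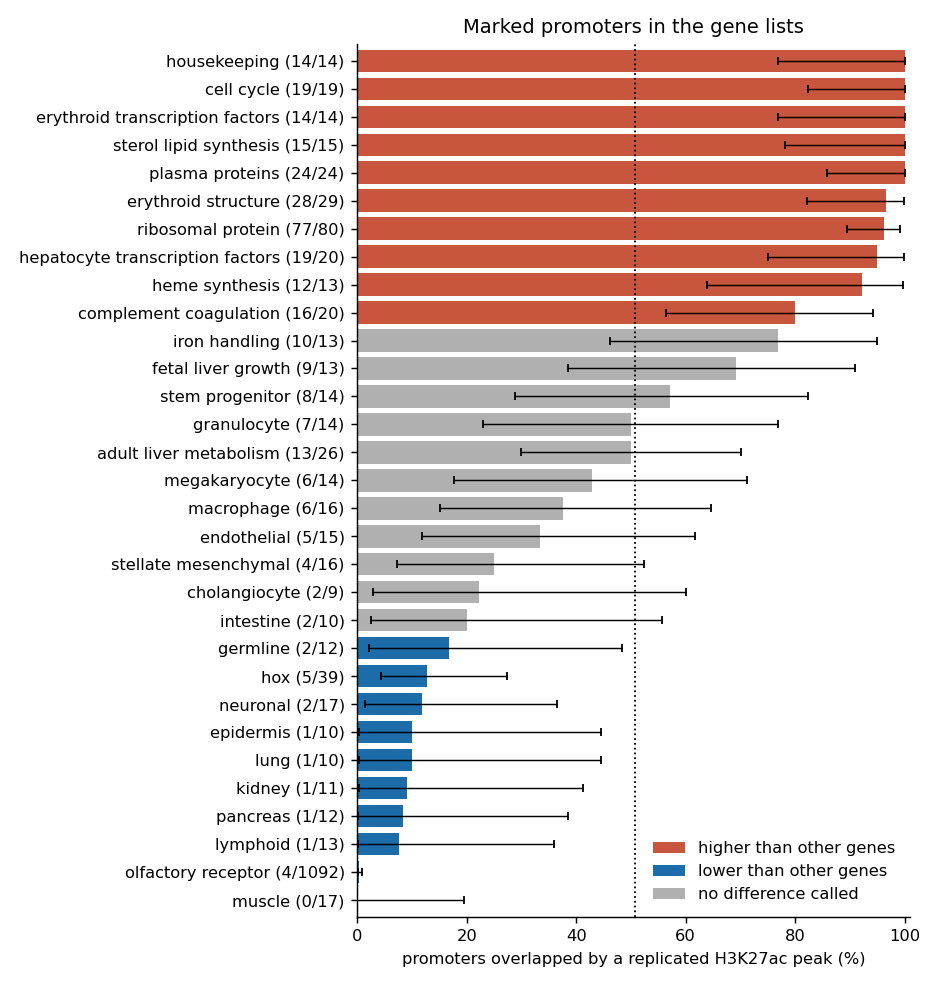
Percentage of promoters marked by a replicated peak in each of the 31 gene lists (horizontal axis), with exact 95% intervals; numbers in brackets are marked and total genes, colours show the call, and the dotted line is the 50.7% of all genes. Erythroid, plasma protein, cell cycle and housekeeping lists stand at or near 100%, and muscle genes at 0%.

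Peaks not wholly within 2 kb of a TSS were joined into 11383 domains. The highest 500 held 50.4% of the signal, the sum of fold enrichment times width by which they were ranked, and 32.5% of the peak bases. Of the 37257 peaks in domains, 3188 overlapped the 2 kb either side of a TSS, among them wide promoter peaks such as those of Zfpm1, Hmbs, Ank1, Alad and Nfe2. The highest domain, on chromosome 11 from 32216450 to 32307639, spanned 91.2 kb with 14 peaks. Its mean fold enrichment, weighted by peak width, was 29.0. The nearest TSS was that of Nprl3, whose introns hold the upstream enhancers of alpha globin, and the domain also held Hba-a1, Hba-a2 and Hba-x. The next lay at Anp32b and Hemgn, Pnpo, Ank1, Sema4b, Hipk2, Zfpm1, Lipc, Ccnd3 and Bcl2l1. Mean fold enrichments, weighted in the same way, were for example 26.1 at Pnpo, 28.1 at Sema4b and 15.5 at Ccnd3. Ranks 11 to 20 were nearest to Rbm38, Lpcat1, Ucp3, Cd24a, Prkar2b, Slc2a1, Cd47, Syngr2, Lmo2 and Hectd4. The beta globin genes Hbb-bh1, Hbb-bs and Hbb-bt overlapped the domain ranked 43, on chromosome 7 from 103806683 to 103879606 with 28 peaks (the globin genes here were named after their values were seen).

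**Figure D3:**
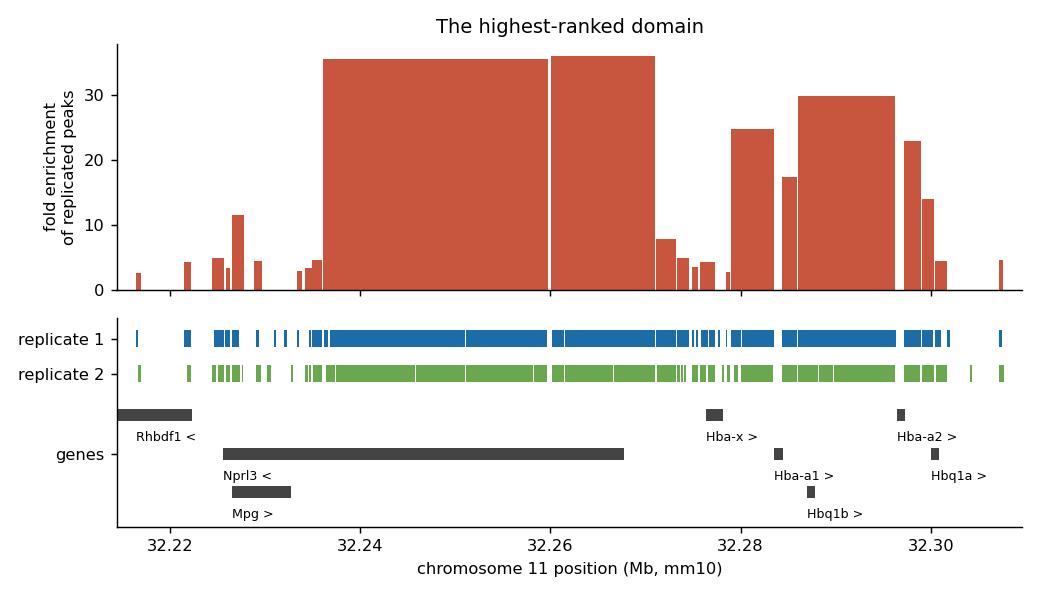
The highest-ranked domain on chromosome 11: fold enrichment of replicated peaks (upper panel, bar width is peak width), and below it the peaks of each replicate and the annotated genes with their strand (horizontal axis in Mb). The tallest bars, up to 36.1, lie over Nprl3 and its 5′ end, and the strongest peaks at the promoters of Hba-a1 and Hba-a2 reach 24.8 and 29.9.

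Genes nearest to the highest 500 domains included 7 of 14 erythroid transcription factor genes (exact adjusted p = 1.36e-07, Fisher's exact test), among them Zfpm1 at rank 7, Lmo2 at 19 and Nfe2 at 98. They included 8 of 29 globin and red cell genes (exact adjusted p = 1.52e-06), such as Ank1 at rank 4, Hbb-bh1 at 43 and Slc4a1 at 44, and 6 of 13 heme synthesis genes (exact adjusted p = 1.52e-06), such as Hmbs at 90, Uros at 254 and Alad at 312. The globin and red cell count rose to 14 of 29 with a 5 kb gap and to 16 among the highest 1000 domains or with any TSS within 25 kb, and the heme count was 4 of 13 with replicate 1's list alone and 3 among the highest 200 domains, all with the call kept. None of 24 plasma protein genes, 20 hepatocyte transcription factor genes, 26 adult liver metabolism genes and 20 complement genes was nearest to one, with 2.27% of other genes, and exact adjusted p was 1 for each of these lists. At that share lists of this size were too small to be called lower, so these counts show no shortage of hepatocyte genes. With a 5 kb gap or with replicate 1's list alone, 1 adult liver metabolism gene and 1 complement gene were nearest to a domain. No hepatocyte list passed under any setting in which the lists were tested. Taken over the 3 erythroid lists, 21 of 56 genes were nearest to a domain, against 1 of 105 genes of the 5 hepatocyte lists (Srebf2; p = 2.04e-10, Fisher's exact test chosen after the lists were seen). Replicate 1's list alone gave 3 of 105 hepatocyte genes (Hpd, Serpinf2 and Srebf2; p = 1.08e-08, Fisher's exact test). With every peak that overlapped the 2 kb either side of a TSS left out, a setting added after the data were seen, the heme synthesis list did not pass (1 of 13, exact adjusted p = 0.827). The erythroid transcription factor list (4 of 14, exact adjusted p = 0.00198) and the globin and red cell list (8 of 29, exact adjusted p = 2.23e-06) passed. There, 13 of 56 erythroid genes stood against 4 of 105 hepatocyte genes (Glul, Hpd, Scd1 and Srebf2; p = 0.000266, Fisher's exact test). Iron handling genes passed with 3 of 13 (Fth1, Slc11a2 and Steap3, exact adjusted p = 0.0173), but not with only replicate 2's list, a 5 kb gap, kept promoter peaks or a background of marked genes, and no member stood among the highest 200 domains or with all promoter peaks left out. The olfactory receptor list was lower (0 of 1092, exact adjusted p = 4.95e-10), a call that ended among marked genes. Housekeeping genes (2 of 14, Actb and Ubc, exact adjusted p = 0.201), sterol genes (1 of 15, exact adjusted p = 1) and lung genes (1 of 10, Sftpb, exact adjusted p = 0.907) did not pass, and the other lists had no gene nearest to a domain. Hbb-bh1, Slc4a1, Hpd, Serpinf2, Scd1, Steap3 and Sftpb were named after their values were seen. Membership of the highest 20 depended on the setting: with a ranking by highest fold 1 of the 20 genes was shared, and with all promoter peaks left out 6 were.

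The replicates were also compared at promoters, as these 2 libraries and not as conditions. Both lists marked 10836 promoters, 91.7% of those marked in either, while 474 were marked in replicate 1's list only and 502 in replicate 2's only. Promoters marked in a single list carried weak peaks, with median fold enrichments of 3.42 (replicate 1) and 3.30 (replicate 2), against 10.4 and 9.90 for shared promoters within the same lists. The 3 lists with at least 5 such genes were megakaryocyte genes (3 in replicate 1's list only and 3 in replicate 2's only), granulocyte genes (2 and 3) and olfactory receptor genes (3 and 4), with an exact adjusted p of 1 for each. With every such gene in a single list, the smallest p multiplied by the 3 lists would be 0.0402, 0.0828 and 0.0198 in the same order (Fisher's exact test). These numbers were therefore too small to show any but an extreme split, and the granulocyte list could not have passed alone.

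The sequence of distal peaks was compared with GC-matched background. The NFE2 consensus was present in 0.765% of windows against 0.312%, a ratio of 2.45 (95% interval 1.97 to 3.04). The ratio was 1.27 (1.24 to 1.30) for GATA, present in 27.2% of windows, and 1.62 (1.45 to 1.80) for the combined E-box and GATA site of TAL1 and GATA1. Among hepatocyte factors it was 1.55 (1.32 to 1.81) for HNF4A, 1.32 (1.25 to 1.39) for FOXA, 1.08 (1.05 to 1.12) for CEBP and 2.33 (1.19 to 4.59) for HNF1, whose call was lost against flanking windows. Ratios of 1.37 for PU.1, 1.62 for ETS, 1.18 for RUNX and 1.11 for KLF1 also passed, and in all 14 of 23 consensus sequences were higher. Consensus sequences chosen for muscle factors were among them, with 1.56 (1.32 to 1.84) for MEF2 and 1.26 (1.16 to 1.36) for MYOD. Which factors bind any of these sequences was not tested, so the ratios do not show in which cell type they act. Shuffled versions of the CEBP, RUNX, ETS and MYOD sequences reached ratios of 1.25, 1.35, 2.43 and 1.43, above those of the sequences themselves. Against flanking windows MEF2 fell to 1.05 (exact adjusted p = 0.526) and SP1 changed from 1.18 to 0.945, while CTCF fell further, to 0.445 (0.404 to 0.490). Flanking windows, 2 kb outside each peak, were not matched on GC content and could lie in other peaks or promoters. NFY (0.668), POU octamer (0.706), CTCF (0.808) and REST (0.1, from 1 against 10 windows) were lower, and NRF1, CDX, NKX2, GRHL and the nuclear receptor site did not pass. Shuffled versions of NFY reached down to 0.367, and those of REST, of which 4 could be counted, to 0, below the sequences themselves. Those of POU octamer and CTCF stayed above them, with lowest ratios of 0.817 and 0.875. The calls of NFY (0.909) and REST (0.25) were lost against flanking windows. In the stronger peaks HNF1 had a ratio of 4.25 (1.43 to 12.6). The CTCF call was lost with replicate 1's list alone (0.920), and GRHL and the nuclear receptor site passed with either replicate's list alone.

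**Figure D4:**
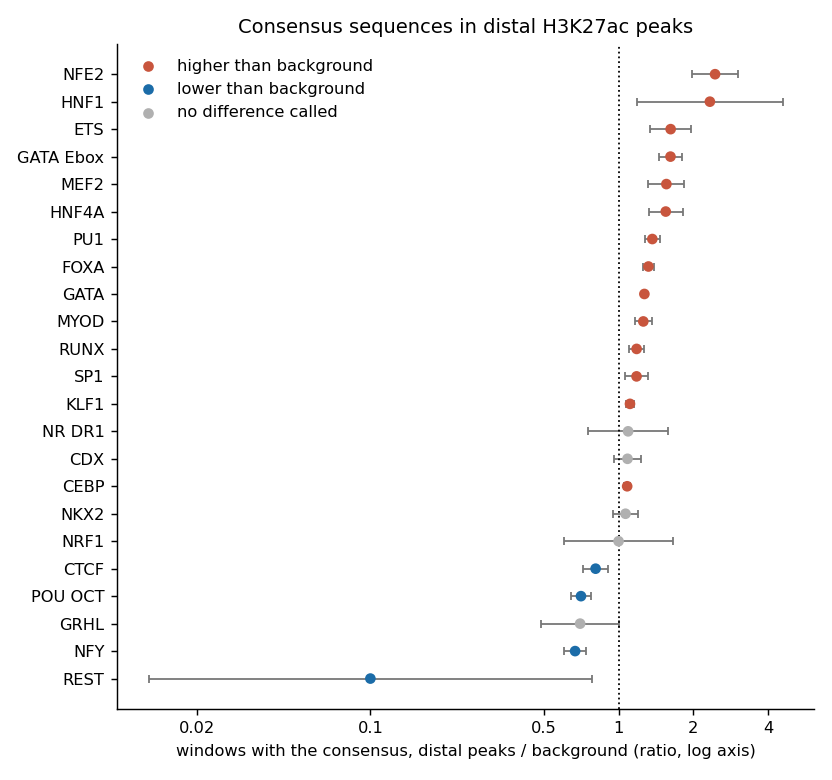
Ratio of distal windows to GC-matched background windows holding each of 23 consensus sequences (horizontal log axis) with 95% intervals; colours show the call. NFE2 (2.45) and HNF1 (2.33) are highest and REST (0.1) lowest.

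The X chromosome held 832 replicated peaks, 4.86 per Mb, against 21.0 per Mb on the autosomes, where single chromosomes ranged from 14.1 (chromosome 14) to 36.4 (chromosome 11). Of X promoters, 29.6% were marked, against 52.1% of autosomal promoters. The X to autosome ratio of peak density was 0.231, and per protein-coding gene it was 0.351. The Y chromosome held 2 replicated peaks.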

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

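The tests of promoter peaks, gene assignment and CpG content, the counts of erythroid against hepatocyte genes and the ratios at summits were chosen after the results were seen.

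The list of replicate 1 held 8 peaks on the mitochondrial genome, with fold enrichments of 1.48 to 1.76, and that of replicate 2 held 0; they stood out because no comparison used them. The replicated list held 6 peaks on unplaced sequences, the strongest with a fold enrichment of 42.2, which were likewise left out.

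Of the genes in the 3 erythroid lists, 21 of 56 lay nearest to one of the highest 500 domains, and of those in the 5 hepatocyte lists 1 of 105 did. Neither the removal of peaks wholly within 2 kb of a TSS nor assignment to the nearest gene was a full account: with those peaks kept 0 of the 5 hepatocyte lists passed the test and 18 erythroid genes stood against 1 hepatocyte gene, and with any TSS within 25 kb counted 0 passed and the shares were 33 of 56 against 7 of 105 genes. Wide promoter peaks in the domains may account for the heme synthesis genes, of which 6 of 13 lay at a domain and 1 of 13 once every peak overlapping the 2 kb either side of a TSS was left out (exact adjusted p = 0.827), and for part of the excess of erythroid transcription factor genes, which fell from 47.8 to 26.4 percentage points, but they were no full account of the other 2 erythroid lists, which still passed. A larger share of red cell precursors than of hepatocytes, a cell mixture, predicted more GATA sites in the domains than in other distal peaks, but the ratio was 0.836 (95% interval 0.790 to 0.883), 0.786 when matched on peak width, where the combined TAL1 and GATA1 site was lower too (0.685, 0.547 to 0.857), and 0.906 at the deposited summits, where the combined site was not called (0.836, 0.671 to 1.04). By the bound written beforehand that prediction failed, since the interval lay below 1. Matched on GC content alone, HNF4A, FOXA, CEBP and HNF1 sites were not called lower. A condition outside that bound, on sites of hepatocyte factors, was then applied. FOXA and CEBP were lower when matched on width (0.848 and 0.893) and at the summits (0.863 and 0.876). SP1 and PU.1 were lower when matched on GC content alone (0.621 and 0.782) and at the summits (0.597 and 0.786). When matched on width SP1 was lower (0.674), but PU.1 was not called (0.836, exact adjusted p = 0.0935). With GC content alone, the interval for HNF4A (0.917, 0.657 to 1.28) spanned that for GATA. With that condition the prediction could not separate the cell types, so the cell mixture stays open. No biological explanation apart from it was tested.

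Peaks were sparse on the X chromosome. Gene content was tested by promoter CpG content: 29.6% of 948 X promoters were marked, below the 40.2% to 45.5% of matched autosomal sets, so CpG content was not a full account. Lower enrichment of each X peak remains a candidate explanation, since 281 marked X promoters had a median fold enrichment of 8.11 and the matched sets 8.40 to 10.6. This value does not tell whether X copy number is a cause. Fold enrichment is read as a ratio over a control library, which may carry the same copy number. No biological explanation was tested, and X inactivation and sequence families with near-identical copies stay open.

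Genes of adult liver metabolism were marked as often as other genes, and a candidate explanation is the CpG content of their promoters. Against lists matched on it they were marked 24.5 percentage points more often (permutation adjusted p = 0.012). Over all genes the share marked ran from 5.08% in the lowest of 10 equal groups by promoter CpG content to 87.8% in the highest.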

How the results depend on the processing

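Of 856 values recomputed under alternatives, 796 were counted as the same, 29 lost a call, 14 gained one, 13 moved and 4 changed direction. The 4 changes of direction were those with a call in at least 1 of the settings compared. Changes of direction without any call were counted as the same, as were counts that changed little. The replicate overlap stayed above shifted lists under all 6 alternatives, marked promoters ranged from 10008 to 11866, and promoter shares of peaks from 19.9% to 35.2%. The background without olfactory receptor genes, the marked-gene background, assignment within 25 kb, long non-coding RNA TSSs, domains without any promoter peak and the ranking by highest fold were added after the data were seen. Differences of lists from other genes are in percentage points. At promoters, a 500 bp window gave 20.0 for complement and −33.3 for germline genes, both without a call, and −50.02 for intestinal genes, with one. A 2 kb window gave −28.5 for lymphoid and −11.6 for lung genes, without a call. The gene's 5′ end alone gave −47.9 for intestinal genes, with a call, and −31.2 for germline genes, without. Peaks with −log10 q of at least 5 gave 21.2 for complement and −32.2 for germline genes, without a call, and −36.4 for stellate genes, with one. The stronger part of the list by fold ended the calls of hepatocyte transcription factors (24.2), complement (9.21) and germline genes (−29.1) and gave calls to iron (31.1), endothelial (−32.5) and stellate genes (−33.3). Lung genes lost the call in the pooled list (−34.3). With a single replicate's list the ranges were 18.3 to 28.1 for complement, 25.1 to 32.9 for fetal growth and −31.9 to −31.8 for lung genes. CpG-matched lists turned adult liver metabolism to 24.5, gave calls to iron (38.8) and stellate genes (−30.1) and ended those of lymphoid (−27.0), lung (−24.6) and epidermal genes (−15.1). Without olfactory receptor genes stellate genes were called (−28.3). At domains, iron genes gave 13.2 with a 5 kb gap, 5.43 with promoter peaks kept, 25.7 among marked genes, −0.907 among the highest 200, −2.19 with all promoter peaks left out and 13.1 to 20.8 with a single replicate. Among marked genes olfactory receptors gave −4.33 without a call and 0 lists were lower. With all promoter peaks left out 2 lists were higher, heme synthesis lost its call (5.50), and 288 of the highest 500 domains and 6 of the 20 genes at the highest were shared. Of the 20 genes at the highest domains, 11 were shared with a 5 kb gap, 13 with ranking by bases, 13 to 14 with a single replicate and 1 with ranking by highest fold, where 320 of the highest 500 domains were shared. The X to autosome ratio was 0.200 in the pooled list and 0.198 to 0.205 with a single replicate. For motifs, flanking windows left 2 lower sequences, with CTCF at 0.445, ended the calls of HNF1 (1.47), NFY (0.909), MEF2 (1.05) and REST (0.25) and turned SP1 to 0.945. In the stronger peaks REST had 0 windows, a ratio of 0. With a single replicate the ratios were 1.38 to 1.45 for the nuclear receptor site, 0.894 to 0.920 for CTCF and 0.637 to 0.726 for GRHL. Smaller lists and fewer peaks shrink each test; beyond that the cause was not tested. Unknown depth limits the weak peaks, of which the replicates shared the least.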

Other observations

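Promoters of long non-coding RNA genes were described after the main results had been seen, as was the choice of the genes named here. Of 13374 such genes, 2547 had a replicated peak within 1 kb of the gene's 5′ end, and of the 10920 away from protein-coding promoters 1094 were marked. Among these were Lockd with a fold enrichment of 43.8, Bloodlinc with 39.8, Mir22hg with 39.2 and Malat1 with 38.8. Mir142hg had 33.0, Redrum had 15.2 and Hnf4aos had 9.43. The mark does not tell strands apart.

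Within the iron and globin lists the values were also compared after they were seen, without a test. Slc11a2 (34.7), Fth1 (33.7), Ftl1 (26.7) and Tfrc (21.1) had the highest fold enrichments among iron genes, Slc40a1 (18.9), Steap3 and Tfr2 (13.7) followed in that order, and Tmprss6 (6.19), Trf (5.59) and Hfe2 (5.01) had the lowest of the marked members. Among globin genes, whose copies are near-identical and whose values are uncertain, the adult genes Hbb-bs (30.9), Hbb-bt (23.4), Hba-a1 (24.8) and Hba-a2 (29.9) stood above the embryonic genes Hbb-bh1 (4.44), Hbb-y (6.38) and Hba-x (4.25).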
